A study of Mus musculus with 8 samples.

How the data were processed

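RNA was measured in 8 samples from C57BL/6 mice that carried the Min mutation of Apc, which gives rise to intestinal tumours. Spint1, the gene for the membrane-bound serine protease inhibitor HAI-1, was flanked by loxP sites in all of them, and a villin-promoter Cre transgene removed it from the intestinal epithelium of the HAI-1 deficient mice. The 4 groups, each of 2 arrays, were non-tumour small-intestinal mucosa and tumours, each from control mice without Cre and from HAI-1 deficient mice. Per the labels, the mice were fed the AIN-76 diet, RNA was isolated with Trizol and a column, and 6 ug of total RNA was labelled with biotin in a single cycle for Affymetrix mouse oligonucleotide arrays. The labels do not say whether the 2 arrays of a group come from different mice, or whether tumour and non-tumour samples come from the same ones, so every p-value measures only the spread between these samples. With 2 arrays per group, the number of arrays limits the precision of every value.

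The deposited table holds 1 value per probe set and array for 45101 probe sets, on the log2 scale. Per the submitters' processing notes, both MAS5 and RMA were used; their versions, order and roles are not given in the sources used here. The values themselves are of the MAS5 kind: after conversion to the linear scale, the mean of each array with 2% of the probe sets trimmed from either end lay between 500.003 and 500.004, and 313 to 762 probe sets per array stood at a lowest log2 value of 0. The distributions differed between arrays, so no quantile normalization had been applied. Detection calls were not used here, so the signal over background of a single value is not known. The table was used as deposited, with no further scaling. Low signals of this kind carry large errors on the log2 scale, which inflates the fitted fold change of a gene that is dim in 1 of the groups.

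Probe sets were assigned to genes with the platform annotation. A single gene was listed for 34958 probe sets, several for 932 and none for 9211, of which 64 are Affymetrix control probe sets. The gene identifiers of 34754 of the single-gene probe sets were found in the reference gene table of mouse assembly GRCm38.p6. Probe set positions in the genome are not given in the sources used here, so no coordinates are reported. Probe sets with a mean log2 signal under the 40th percentile of all probe sets, 5.20 on the log2 scale or 36.8 on the linear scale, were removed. For each gene the single-gene probe set with the highest mean was kept. Of 18194 genes with a single-gene probe set, 13119 were tested.

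A linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation. It had 4 residual degrees of freedom and 3.52 prior degrees of freedom. The 7 contrasts were HAI-1 loss in non-tumour mucosa, in tumours and averaged over both tissues; tumour against non-tumour tissue in control mice, in HAI-1 deficient mice and averaged over both genotypes; and the interaction, which is the effect of HAI-1 loss in tumours minus that in non-tumour mucosa. Tests were two-sided, p-values were adjusted over genes by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Fold changes are given as log2 differences with the standard error of the fit. Where the lower group's mean or 1 of its arrays lay under the filter value of 5.20, the change is given, alone or beside the fitted value, with each such array raised to that value, as at least so much. Figures were drawn with python 3.11.15.

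The 40 gene lists were tested with camera at a preset inter-gene correlation of 0.01, on the tested members of each list, and p-values were adjusted over the 40 lists within a contrast. Each list had at least 3 tested genes. Beside camera, the same test with a correlation estimated from the data and fry were run. Of the 280 pairs of list and contrast, 116 were called with the preset correlation and 0 with the estimated one. The lists cover cell types of the small intestine and its wall, pathways of intestinal tumours, immune responses, metabolism, the HAI-1 protease network and checks of sex and of attached pancreas. The lists, the filter, the tests, the rule for named genes and the alternatives were, with exceptions, chosen before the data were examined. Exceptions are 2 alternatives, named with the results that depend on the processing, and some tests, named with the results flagged for a closer look.

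Named genes were picked by rule. Spint1 was always named. For each contrast, the 10 genes with the largest rise and the 10 with the largest fall were named among those with an adjusted p under 0.05, a log2 fold change of at least 1 in size and no overlap between the arrays of the groups compared, leaving out gene models without a descriptive symbol. Where none passed, the 5 genes with the smallest p in each direction were named, as values. Members of the lists were named as examples of their list by their p.

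The fit was tested on simulated data with 13119 genes, 200 of them changed. At a log2 change of 1, 2, 3 and 4, HAI-1 loss in non-tumour mucosa recovered 2%, 54%, 76% and 98% of the changed genes, with 7 false calls among 122. HAI-1 loss in tumours recovered 0%, 54%, 86% and 92% (5 false of 121), and its average over tissues 20%, 90%, 94% and 98% (12 of 163). Tumour against non-tumour tissue recovered 0%, 42%, 84% and 90% in control mice (8 of 116), 2%, 70%, 84% and 100% in HAI-1 deficient mice (6 of 134), and 16%, 90%, 96% and 100% averaged over genotypes (7 of 158). The interaction recovered 0%, 6%, 54% and 84% (2 of 74). A list given a shift ranked 1 of 40, and 0 other lists were called. The simulated genes varied independently of each other, with normal errors whose size did not depend on the signal. This does not show how the list test behaves with correlated members, nor the share of false calls among the genes called in the real data.

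The alternatives were quantile normalization, no filter, a filter at the 60th percentile, a mean-variance trend in the moderation, the mean of all probe sets of a gene, leaving out probe sets whose name ends in _x_at, fits to only the groups compared, array weights, a block for the replicate number and each array left out in turn. A comparison of Spint1 between the 4 deficient and 4 control arrays used an exact permutation test. Differences between the mean changes of 2 lists used a permutation test with 100000 resamples over genes. Covariances between contrasts that share their control arrays were compared with those in 100 simulations of groups without change. Probe sets with several genes or none were tested apart and are reported with the results that call for a closer look.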

Results

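Gene expression was measured with 8 Affymetrix arrays in Apc mutant mice with or without HAI-1 in the intestinal epithelium, with 2 arrays per group. The 4 groups were control non-tumour mucosa, HAI-1 deficient non-tumour mucosa, control tumours and HAI-1 deficient tumours. Of 45101 probe sets, 34958 had a single listed gene, and 13119 genes were tested. Pearson's r across the 13119 tested genes was 0.947 to 0.968 between arrays of a group, 0.915 to 0.976 within a tissue and 0.830 to 0.920 between tissues. Genes are not independent replicates. The first principal component held 58.3% of the variance and ran from control non-tumour mucosa (scores -85.2 and -80.9) through HAI-1 deficient non-tumour mucosa (-28.8 and -21.2) to the tumours (51.0 to 57.0). The second array of control tumours had a Gapdh 3' to 5' signal ratio of 25.9, against 0.803 to 1.77 on the other 7 arrays, as can be seen with degraded RNA. Its Actb ratio was 2.32, against 1.15 to 1.52 on the others, so the rise was far smaller by this control. Poly-A spike-in signal was 9.17 to 9.42 log2 on the second array of control non-tumour mucosa, deficient non-tumour mucosa and deficient tumours, and 7.69 to 7.96 on the other 5 arrays. This split was treated as a labelling batch that the labels do not name. The 18S ribosomal RNA control signal was 14.60 and 13.63 log2 on the second arrays of control and deficient non-tumour mucosa. On the other arrays it was 7.61 to 10.07, with the lowest value on the second deficient tumour array. Whether the arrays with high spike-in signal form 1 batch is thus not known.

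Spint1, the targeted gene, was lower in every HAI-1 deficient array than in every control array. Its log2 signal was 12.87 and 13.00 in control non-tumour mucosa, 12.75 and 13.06 in control tumours, 12.46 and 12.25 in deficient non-tumour mucosa, and 11.76 and 11.84 in deficient tumours. The 4 deficient arrays differed from the 4 controls by -0.84 log2 (exact permutation test over 70 assignments regardless of tissue, two-sided p = 0.0286, the smallest p this test can give). Assignments within each tissue are fewer, so their smallest p would be larger, and that test was not run. With limma the difference was -0.58 ± 0.24 in non-tumour mucosa (SE, n = 2 per group, adjusted p = 0.271), -1.10 ± 0.24 in tumours (0.779) and -0.84 ± 0.17 averaged over tissues (0.118). Spint1 was not called in any of the 3. With a mean-variance trend the average passed, at an adjusted p of 0.0401. Spint1 differed by -0.41 and -0.75 log2 in non-tumour mucosa within the low and the high spike-in batch, and by -1.14 in tumours within the low batch. The position of the probe set relative to the floxed exons is not given in the sources used here, and the mucosa also holds cells in which villin-Cre does not act.

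**Figure D1:**
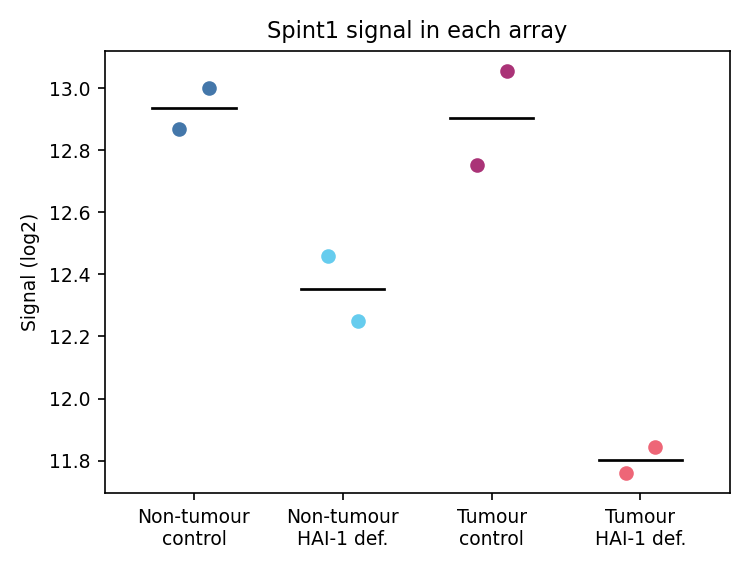
Log2 signal of Spint1 (vertical axis) in each of the 8 arrays, by group (horizontal axis), with points for arrays and bars for group means. The highest deficient array, at 12.46, lies below the lowest control array, at 12.75.

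HAI-1 loss in non-tumour mucosa, the comparison of deficient with control mucosa outside tumours, gave 138 called genes, of which 118 rose and 20 fell. Among the largest rises were Chil3, a chitinase-like protein of myeloid cells (5.60 ± 0.48 log2, SE, n = 2 per group, at least 2.15-fold, adjusted p = 0.0139), and Hp, the acute-phase protein haptoglobin (4.95 ± 0.60, at least 2.57-fold, adjusted p = 0.0348). Rises also took in Cyp2d10, a cytochrome P450 (at least 4.16-fold), the carbonyl reductase Cbr3 (at least 14.0-fold), the chemokine Cxcl17 (at least 6.47-fold) and the metalloprotease Pappa (at least 5.35-fold). Eya2, Tmem45a, Cldn18 and Sgce rose at least 1.66-, 3.44-, 2.72- and 2.34-fold. The 2 probe sets of Cldn18 differed, at -0.23 and 3.65 log2, and their mean was not called (1.71, adjusted p = 0.245). All 10 of these had a mean under the filter value in control mucosa, so their folds are lower bounds. The largest falls were those of Dio1, the deiodinase that activates thyroid hormone (-5.17 ± 0.70, 35.9-fold), and Ubd, a ubiquitin-like modifier induced by interferon-gamma (-4.90 ± 0.47, 29.9-fold, adjusted p = 0.0148). Ido1, an interferon-induced enzyme of tryptophan breakdown, fell by 3.53 ± 0.49 log2, the potassium channel gene Kcnj13 by 3.47 ± 0.50, Afp by 3.44 ± 0.50, and Herc6 by 3.30 ± 0.45. Tppp was at least 10.6-fold lower. With the mean of probe sets the calls of Cbr3, Eya2, Dio1, Tppp, Ido1 and Kcnj13 ended (adjusted p = 0.0502 to 0.0681) at an unchanged fitted value, and that of Afp at -2.44 (0.0638).

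Interferon-induced genes shifted down in deficient non-tumour mucosa (camera, adjusted p = 1.88e-17, median -1.91 log2; adjusted p = 0.313 with an estimated correlation). Of 23 members 4 fell and 19 did not pass, or 15 fell adjusted over the list alone. The 4 were Oas3 (at least 12.2-fold lower), Oasl2 (-3.10 ± 0.42), Usp18 (-3.31 ± 0.49, adjusted p = 0.0395) and Ifit1 (-3.13 ± 0.49, adjusted p = 0.0435). The calls of Usp18 and Ifit1 ended with quantile normalization (0.0594 and 0.0663) and with the mean of probe sets (0.0579 and 0.0611). Genes of MHC class II presentation shifted down as well (median -2.06; adjusted p = 0.313 with an estimated correlation). H2-DMa (-2.07 ± 0.28), H2-Ab1 (-2.26 ± 0.32) and H2-Eb1 (-2.06 ± 0.33) fell, 4 of the 7 did not pass, and 6 fell adjusted over the list alone. Markers of T and natural killer cells had a median of -1.18, with 0 of 16 called over all genes by limma and 8 lower adjusted over the list alone, among them Il2rb (-1.68 ± 0.33) and the granzyme Gzmb (-1.47 ± 0.32). The list shifted down, at an adjusted p = 0.313 with an estimated correlation. Mast cell (median -1.35), B and plasma cell (-0.45) and tuft cell (-0.68) markers had 0 calls over all genes and 0 adjusted over the list alone. These 3 lists also shifted down, with an adjusted p with an estimated correlation of 0.551, 0.551 and 0.399. The immediate early genes Fosb (at least 2.89 log2 lower) and Atf3 (-1.94 ± 0.33) fell in a list with a median of -0.36 (adjusted p = 0.376 with an estimated correlation), while 12 of 14 members did not pass. Adjusted over the list alone, 1 was higher and 2 lower. Smaller downward shifts, with 0 members called over all genes, were seen for enterocyte (median -0.05, adjusted p = 0.583 with an estimated correlation), ileal (-0.49, 0.313), enteroendocrine (-0.15, 0.583) and endoplasmic reticulum stress genes (-0.22, 0.551). Adjusted over the list alone, 0, 1, 1 and 1 of them were lower, and the calls of the enterocyte and stress lists ended with quantile normalization (adjusted p = 0.0626 and 0.0627).

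Wnt and beta-catenin targets shifted up in deficient non-tumour mucosa (camera, adjusted p = 1.35e-08, median 1.52 log2; adjusted p = 0.327 with an estimated correlation). The Wnt feedback inhibitor Notum (2.33 ± 0.31), Ifitm1 (2.16 ± 0.28) and Ifitm3 (1.72 ± 0.25) rose, 20 of 23 did not pass, and 11 rose adjusted over the list alone. Of 10 fetal-like regenerative genes, Clu (2.33 ± 0.31) and Anxa1 (1.80 ± 0.27) rose, or 7 adjusted over the list alone (median 1.31; adjusted p = 0.313 with an estimated correlation). Of 16 hypoxia-induced and glycolytic genes, the carbonic anhydrase Car9 (1.77 ± 0.26) and the glucose transporter Slc2a1 (1.97 ± 0.32) rose, or 6 over the list alone (median 0.86; adjusted p = 0.313 with an estimated correlation). The matrix protease Mmp14 rose by 1.84 ± 0.27, alone among 18 matrix genes over all genes and 1 of 10 adjusted over the list alone (median 1.32; adjusted p = 0.313 with an estimated correlation). Cholesterol synthesis (median 0.96) and fibroblast genes (1.16) had 0 calls over all genes, whereas adjusted over the list alone 8 and 11 were higher and, among fibroblast genes, 1 lower. Their adjusted p with an estimated correlation was 0.327 and 0.313. The angiopoietin receptor gene Tek (at least 2.21 log2 higher) rose among 13 endothelial markers (median 0.90, 5 over the list alone; adjusted p = 0.327 with an estimated correlation) and Myl9 (2.59 ± 0.39) among 12 smooth muscle genes (0.85, 3; 0.579). Stem cell markers (median 0.58) and cell cycle genes (0.51) shifted up with 0 called members by limma over all genes and 2 and 1 adjusted over the list alone. Their adjusted p with an estimated correlation was 0.551 and 0.711. Outside these lists' shifts, the plasminogen activator Plat (2.56 ± 0.42), the claudin Cldn2 (2.40 ± 0.28) and the acyl-CoA thioesterase Acot1 (3.14 ± 0.26) rose.

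The other 19 lists were not called by camera in this comparison, including the HAI-1 protease network (median 0.27), goblet (0.04), Paneth (0.27), tight junction (0.07), NF-kappaB (-0.01), macrophage (-0.02), neutrophil (0.81) and oxidative phosphorylation (-0.08) genes. Medians were 0.19 for proximal intestinal, 0.16 for antimicrobial, 0.12 for p53 target, 0.55 for epithelial-mesenchymal transition, -0.20 for circadian, 0.19 for PPAR-alpha, -0.13 for xenobiotic, -0.07 for eosinophil, 0.38 for neuron and glia, -0.18 for pancreatic and -0.34 for sex-linked genes. Adjusted over the list alone, 3 PPAR-alpha, 2 neutrophil and 1 each of the protease network, junction, macrophage and pancreatic genes were higher. The sign of the median, the mean and the test differed for the goblet, Paneth, junction, NF-kappaB, antimicrobial, xenobiotic, macrophage and pancreatic lists. By limma 2295 of the 13119 genes had an unadjusted p under 0.05. By fry 11 of the 40 lists were called. Within the low and the high spike-in batch, each with 1 array per group and hence no test, the interferon median was -1.57 and -2.08, the T and natural killer median -1.11 and -1.23 and the fibroblast median 1.21 and 0.87. With a batch term 130 genes were called. The count was 46 with quantile normalization, 0 without the filter, 331 with the 60th percentile filter, 370 with a mean-variance trend, 24 with the mean of probe sets and 46 in a fit to only the groups compared. It fell to 0 without either deficient non-tumour array, to 7 and 3 without the first and the second control non-tumour array, and to 11 without either control tumour array.

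Leaving out single arrays also ended list calls in this comparison. Without the second deficient non-tumour array the stem cell, enterocyte, enteroendocrine, tuft, cell cycle, ileal, stress and B and plasma cell calls ended, at medians of 0.29, 0.05, 0.09, -0.16, 0.27, -0.21, -0.10 and -0.19. The Wnt target, smooth muscle and immediate early medians were 0.93, 1.29 and -0.21 then. Without the first deficient array the smooth muscle and mast cell calls ended (0.32 and -1.59), and the enterocyte, enteroendocrine, cell cycle, stress, B and plasma cell and endothelial medians were -0.18, -0.39, 0.81, -0.42, -0.86 and 1.51. Without the first control array the stem cell, enteroendocrine, tuft and cell cycle calls ended (0.43, -0.14, -0.40 and 0.22), and the enterocyte median was -0.12. Without the second control array the enterocyte, ileal, stress, immediate early, smooth muscle and B and plasma cell calls ended (-0.07, -0.57, -0.11, -0.22, 0.60 and -0.17), and the enteroendocrine and cell cycle medians were -0.27 and 0.89. The enterocyte call also ended without either deficient tumour array (adjusted p = 0.0524).

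**Figure D2:**
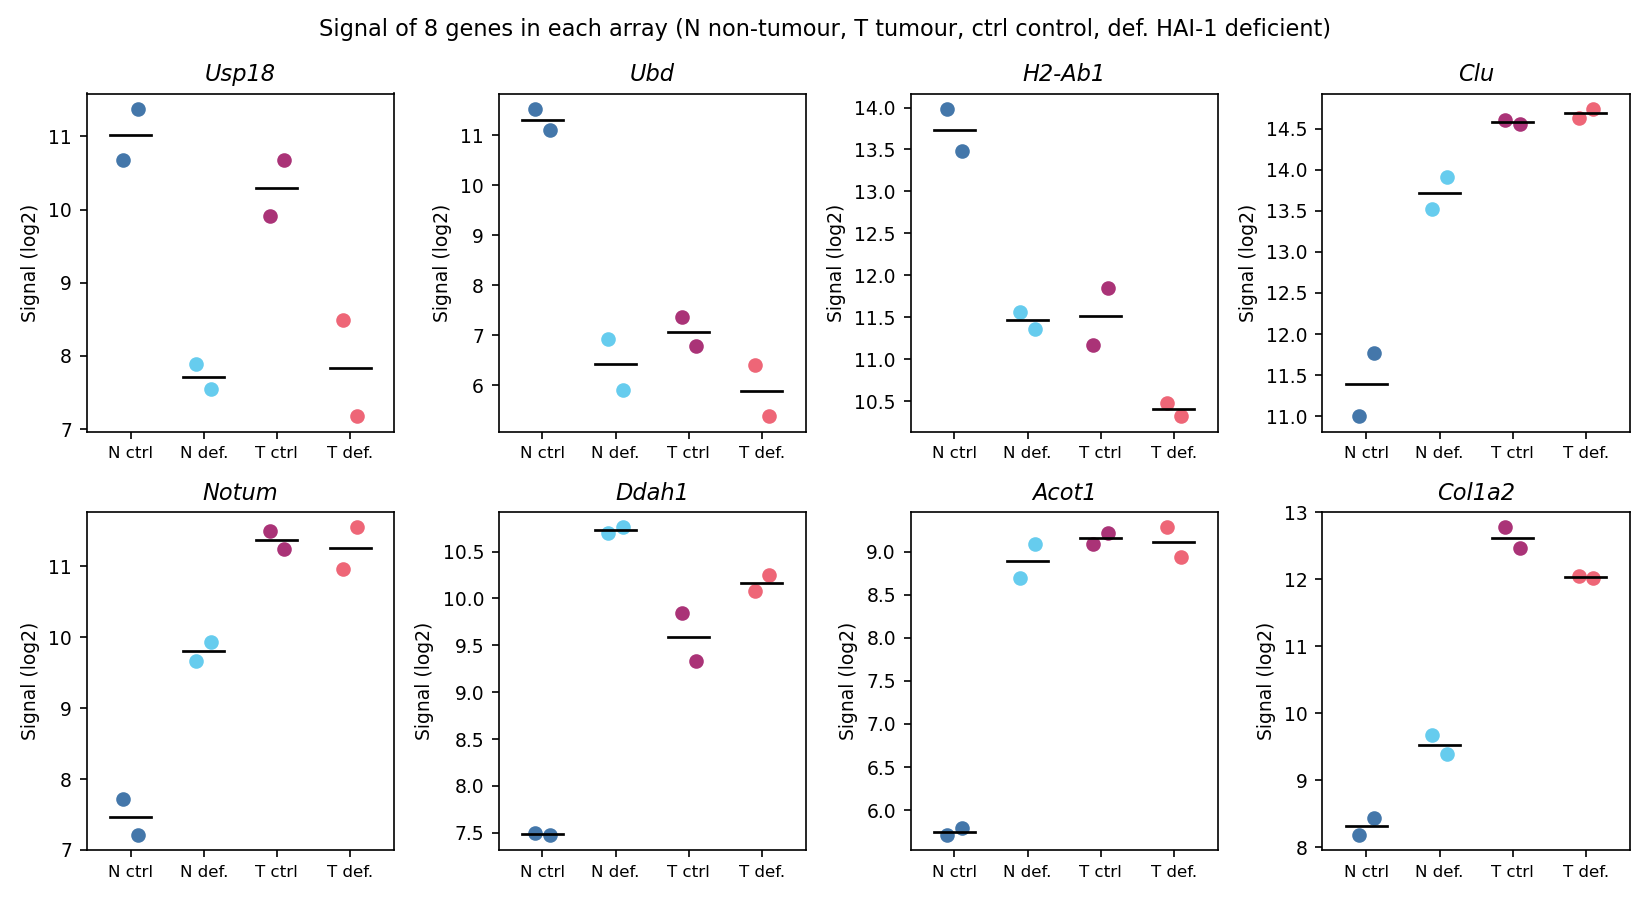
Log2 signal (vertical axes) of 8 genes in each array, by group (horizontal axes: N non-tumour, T tumour, ctrl control, def. HAI-1 deficient), with points for arrays and bars for group means. In non-tumour mucosa Usp18, Ubd and H2-Ab1 were lower in both deficient arrays, and Clu, Notum, Ddah1 and Acot1 higher, while Col1a2 (1.21 ± 0.25 log2) was not called.

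HAI-1 loss in tumours, the comparison of tumours that formed with and without the inhibitor, gave 0 called genes by limma at a smallest adjusted p of 0.779, with 802 genes at an unadjusted p under 0.05. Fry called 0 of the 40 lists. The genes with the smallest p had log2 differences of -3.03 ± 0.49 for Ifit1, -2.46 ± 0.49 for Usp18, -1.56 ± 0.32 for Gzmb, -1.41 ± 0.26 for the neuropeptide Vip and -1.40 ± 0.30 for the peptide transporter Slc15a1 (SE, n = 2 per group, adjusted p = 0.779 each). In the other direction they were Nlrp10, the gastric lipase Lipf, Tmem126b, Zpbp2 and Cbx3. With 1 or both control tumour arrays under the filter value, these were at least 4.49-, 7.99-, 2.28-, 1.32- and 1.65-fold higher. Interferon-induced genes shifted down (camera, adjusted p = 6.28e-12, median -1.11; adjusted p = 0.463 with an estimated correlation), with 7 of 23 lower adjusted over the list alone. MHC class II genes (median -1.11, 3 of 7 over the list alone), T and natural killer markers (-0.85, 6 of 16) and mast cell markers (-1.72, 3 of 8) shifted the same way, each with an adjusted p = 0.463 with an estimated correlation. Examples were H2-Ab1 (-1.11 ± 0.32), the mast cell carboxypeptidase Cpa3 (-1.99 ± 0.62) and Fcer1a (-2.60 ± 0.79). Fibroblast genes also shifted down (median -0.64, 0 of 16 over the list alone; adjusted p = 0.255 with an estimated correlation), as did epithelial-mesenchymal transition genes (-0.76, 4 of 9; 0.370). Col5a2 was -0.78 ± 0.27 and Zeb1 -0.90 ± 0.28. Enterocyte (median -0.23, 1 of 26 over the list alone), goblet (-0.35, 0 of 14) and NF-kappaB genes (-0.39, 0 of 25) were lower and hypoxia genes (0.32, 0 of 16) higher as lists. Their adjusted p with an estimated correlation was 0.749, 0.463, 0.773 and 0.463, and the enterocyte and goblet calls ended with quantile normalization (adjusted p = 0.109 and 0.101). With the mean of probe sets the NF-kappaB and hypoxia calls ended, at medians of -0.12 and 0.37 (camera, adjusted p = 0.0770 and 0.0665). Within the low spike-in batch, with 1 deficient and 2 control arrays, the median was -0.39 for interferon, -0.53 for T and natural killer and -0.69 for fibroblast genes. The array with the high Gapdh ratio is 1 of the 2 controls here. Without the second deficient tumour array, which is the one of the high spike-in batch, the NF-kappaB, goblet and hypoxia calls ended (medians -0.22, -0.11 and 0.16). The interferon, mast cell, T and natural killer and enterocyte medians were -0.39, -0.65, -0.53 and -0.39 then. The mean signal of the mast cell list was 8.32 log2 on that array and 10.40 on the other deficient one, against 11.03 and 10.90 in controls. Without the first deficient tumour array the enterocyte call ended (0.04), and the interferon, mast cell and hypoxia medians were -1.88, -2.98 and 0.48. Without the first control tumour array the NF-kappaB, enterocyte, goblet and hypoxia calls ended (0.08, -0.14, -0.32 and 0.24), and without the second the enterocyte median was -0.37. The NF-kappaB call also ended without either control non-tumour array (adjusted p = 0.0558).

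Averaged over tissues, 0 genes were called for HAI-1 loss by limma, at a smallest adjusted p of 0.0599, and 2136 had an unadjusted p under 0.05. Fry called 2 lists. The smallest p belonged to interferon-induced and antigen presentation genes on the lower side, with Ifit1 at -3.08 ± 0.35 log2, Ubd at -3.04 ± 0.33, Usp18 at -2.89 ± 0.35, Herc6 at -2.59 ± 0.32 and H2-DMa at -1.59 ± 0.20 (SE, n = 4 arrays per genotype, adjusted p = 0.0599 each). On the higher side they were Ddah1 (1.91 ± 0.18), an enzyme that clears an inhibitor of nitric oxide synthesis, Ak4 (1.84 ± 0.21), Acot1 (1.55 ± 0.18), Chst14 (at least 0.86 log2) and Tnnt2 (at least 1.35 log2). The last 2 had a mean under the filter value in control non-tumour mucosa. With the mean of probe sets Ak4 was at 0.89, Tnnt2 at 0.86 and H2-DMa at -1.0015. Interferon-induced genes shifted down (camera, adjusted p = 6.06e-20, median -1.46; adjusted p = 0.408 with an estimated correlation) with 18 of 23 lower adjusted over the list alone. MHC class II (-1.39, 6 of 7 over the list alone; 0.408), T and natural killer (-1.09, 13 of 16; 0.408) and mast cell genes (-1.61, 5 of 8; 0.501) also shifted down, the last value being the adjusted p with an estimated correlation. Wnt targets (0.81, 14 of 23; 0.501), fetal-like (0.67, 5 of 10; 0.408), hypoxia (0.59, 5 of 16; 0.408), cholesterol synthesis (0.60, 7 of 15; 0.501), matrix (0.50, 3 of 18; 0.540) and endothelial genes (0.45, 2 of 13; 0.501) shifted up, with the same values in the same order. Enterocyte, ileal, oxidative phosphorylation and B and plasma cell genes had medians of -0.18, -0.31, -0.12 and -0.51 and shifted down, with 0, 1, 0 and 0 lower over the list alone. Their adjusted p with an estimated correlation was 0.501, 0.408, 0.700 and 0.501. The calls of the ileal and oxidative phosphorylation lists ended with quantile normalization (adjusted p = 0.0721 and 0.151). The count of genes was 31 with the 60th percentile filter, 116 with a mean-variance trend, 1 with the mean of probe sets and 19 with array weights. Without the first deficient tumour array it was 221 and without the second 4. The ileal, oxidative phosphorylation and B and plasma cell calls ended without the second control non-tumour array (medians -0.36, -0.09 and -0.40) and, with the endothelial call, without the second deficient one (-0.44, -0.09, -0.27 and 0.38). Without the second deficient tumour array the ileal and oxidative phosphorylation calls ended (-0.27 and -0.08), and the mast cell and B and plasma cell medians were -1.03 and -0.31. Without the first the enterocyte and matrix calls ended (-0.09 and 0.47), and the ileal and oxidative phosphorylation medians were -0.62 and -0.19. Without the second control tumour array the oxidative phosphorylation and matrix calls ended (-0.02 and 0.36). Without the first the ileal, oxidative phosphorylation, enterocyte and endothelial medians were -0.50, -0.22, -0.10 and 0.70. The cholesterol synthesis median was 0.37 without the first control non-tumour array and the ileal median -0.47 without the first deficient one.

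**Figure D3:**
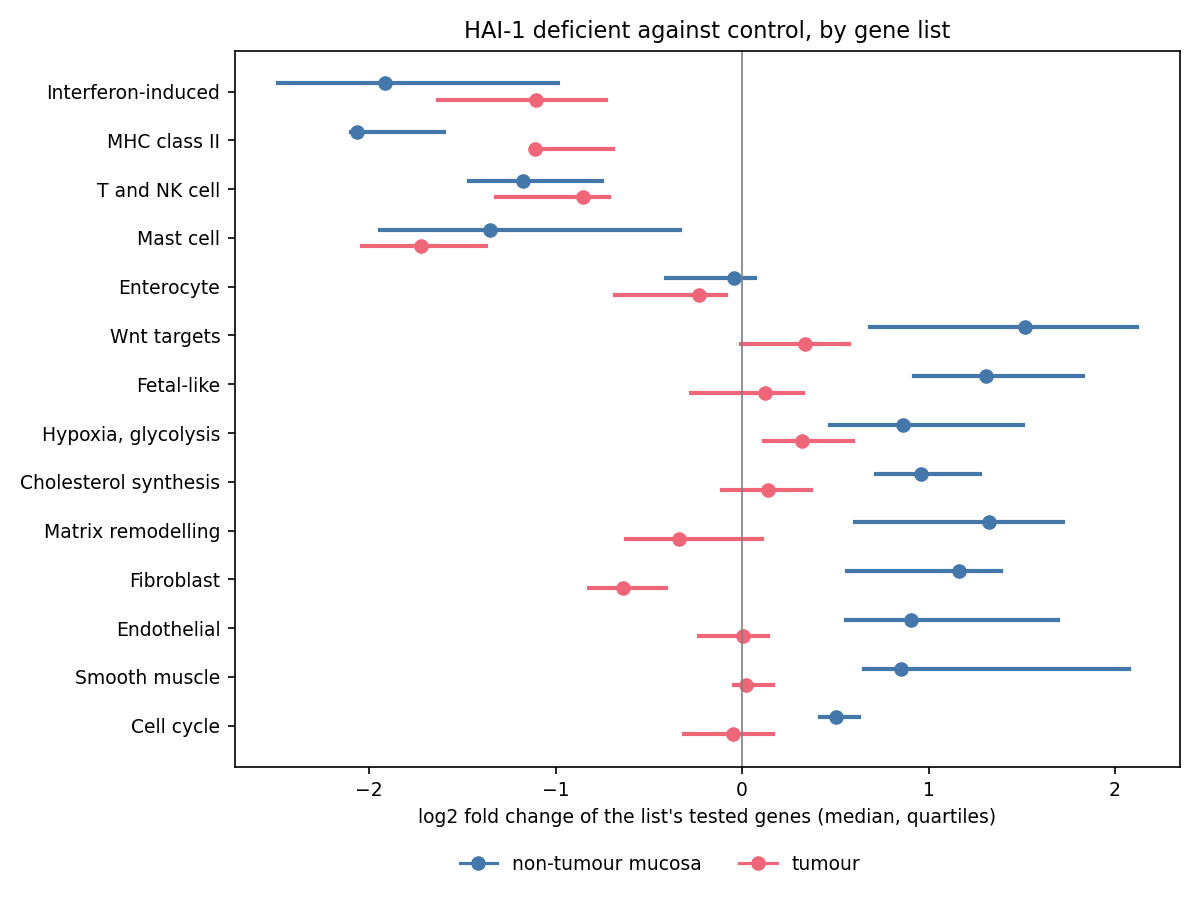
Median log2 difference of HAI-1 deficient against control tissue (horizontal axis) over the tested genes of 14 lists (vertical axis), in non-tumour mucosa and in tumours, with lines from the first to the third quartile of genes. Interferon-induced genes had medians of -1.91 and -1.11, and fibroblast genes of 1.16 and -0.64.

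Tumour against non-tumour tissue in control mice, the comparison of what tumours express in the presence of HAI-1, gave 3777 called genes, of which 2775 were higher and 1002 lower in tumours. The largest rises included acute-phase and plasma proteins, namely Hp (8.24 ± 0.60 log2, SE, n = 2 per group, at least 25.2-fold, adjusted p = 0.000866), Alb (at least 20.4-fold) and Serpina3n (at least 33.4-fold). Tff2, a trefoil peptide of gastric mucous cells, rose by at least 6.60 log2, and Retnlb, a goblet cell resistin-like protein, by 6.72 ± 1.60 (adjusted p = 0.0195). Nptx2 rose at least 50.8-fold, Tmem45a at least 46.1-fold, the procollagen processing gene Pcolce2 at least 21.1-fold, Chil3 at least 6.83-fold and Eya2 at least 5.96-fold. Falls included sodium-coupled transporters, namely Slc5a12 (at least 5.19 log2, adjusted p = 0.0454), Slc5a4b (at least 5.03 log2), Slc5a4a (-4.49 ± 1.04), Slc5a8 (at least 3.77 log2) and Slc34a2 (-4.52 ± 1.42). Cubn, which takes up vitamin B12 bound to intrinsic factor, fell by 4.23 ± 0.71 log2, Dnase1 by 4.46 ± 1.32, Cenpb at least 7.91-fold and Ubd by 4.25 ± 0.47, while the retinol dehydrogenase Rdh16 was at least 5.85-fold lower. Several of these falls rested on the second control tumour array, with the high Gapdh ratio, such as those of Slc5a12 (9.17 and 0.51 log2 on the 2 tumour arrays) and Cenpb (6.64 and 1.26), whose tumour means it brought under the filter value. Without it Slc5a12 was at -3.21 and Slc5a4b at -3.47, and the calls of Slc5a4a (-3.10), Slc5a8 (-2.12), Slc34a2 (-2.31), Dnase1 (-2.46), Cenpb (-2.27) and Retnlb (4.81) ended. Without the first control tumour array, Slc5a12, Slc5a8 and Cenpb lay under the filter value on the array left and were lower by at least 7.17, 5.42 and 3.70 log2. Without the first control non-tumour array the same 6 calls and that of Slc5a12 ended (adjusted p = 0.0521 for Slc5a4a, 0.100 for Retnlb and 0.125 to 0.230 for the others). Without the second those of Slc5a12, Slc5a4a, Slc5a8, Dnase1 and Cenpb ended (0.0838 to 0.151). Slc5a12, Slc34a2 and Cenpb were also not called without any 1 of the 4 deficient arrays (0.0596 to 0.0726), nor Dnase1 and Slc5a8 without either deficient non-tumour array (0.0580 and 0.0587).

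In control mice 17 of 23 Wnt targets rose in tumours, or 18 adjusted over the list alone, with Notum at 3.90 ± 0.31 log2, Cd44 at 3.35 ± 0.28 and Ifitm3 at 3.05 ± 0.25 (median 2.41; adjusted p = 0.365 with an estimated correlation). Among stem cell markers 9 of 16 rose, or 10 over the list alone, with Lgr5 at 3.42 ± 0.48 (median 1.72; adjusted p = 0.365 with an estimated correlation). Cell cycle genes rose in 24 of 29, or 27 over the list alone, such as Cdc6 (1.79 ± 0.25) and Mcm7 (1.90 ± 0.28), with a median of 1.83 (adjusted p = 0.432 with an estimated correlation). All 10 fetal-like genes rose, also over the list alone, with Anxa1 at 3.31 ± 0.27 and Clu at 3.20 ± 0.31 (median 2.53; adjusted p = 0.225 with an estimated correlation). Matrix genes rose in 17 of 18 (Timp1 3.62 ± 0.30, Mmp13 3.65 ± 0.33) and fibroblast genes in 15 of 16 (Col1a2 4.30 ± 0.25, Dcn 4.36 ± 0.34), or 18 and 15 over the list alone. Their medians were 3.23 and 2.86 and their adjusted p with an estimated correlation 0.225 and 0.162. Smooth muscle genes rose in 11 of 12 (Acta2 3.29 ± 0.38), endothelial markers in 7 of 13 (Vwf 2.83 ± 0.48), epithelial-mesenchymal transition genes in 6 of 9 (Zeb1 2.67 ± 0.28) and mast cell markers in 6 of 8 (Cpa3 3.97 ± 0.62). Over the list alone 11, 8, 7 and 8 rose and 1 transition gene fell, the medians were 3.19, 1.53, 2.84 and 3.89, and the adjusted p with an estimated correlation was 0.365, 0.365, 0.225 and 0.374. Of 15 cholesterol synthesis genes 8 rose, or 11 over the list alone, such as Sqle at 1.69 ± 0.34 (median 1.19; adjusted p = 0.512 with an estimated correlation).

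On the lower side, 13 of 26 enterocyte genes fell in control tumours, or 14 over the list alone (median -1.09, adjusted p = 0.225 with an estimated correlation). Among them were the peptidases Dpp4 at -2.39 ± 0.38 and Anpep at -3.17 ± 0.66. Anpep was 11.65 and 9.46 log2 on the first and the second control tumour array, against 13.5 and 14.0 in control mucosa. The size of its fall thus rests in part on the second, with the high Gapdh ratio. Ileal genes fell in 4 of 7, also over the list alone (median -2.19, 0.225 by the same test), and enteroendocrine genes in 5 of 19, also over the list alone (-1.12, 0.365), with the hormone genes Nts at -3.53 ± 0.45 and Gip at -2.55 ± 0.32. MHC class II genes fell in 5 of 7, also over the list alone, with H2-DMa at -2.41 ± 0.28 (median -2.22; adjusted p = 0.225 with an estimated correlation). T and natural killer markers fell in 5 of 16, with Cd8a at -1.57 ± 0.26, while over the list alone 8 were lower and 1 higher (median -1.08; adjusted p = 0.365 with an estimated correlation). Interferon-induced genes fell in 3 of 23, or 2 over the list alone, namely Igtp, Psmb8 and Psmb9 (-2.72 ± 0.41, -2.07 ± 0.46 and -2.23 ± 0.60; list median -0.44; adjusted p = 0.578 with an estimated correlation). Of 21 xenobiotic metabolism genes 10 fell and 2 rose, also over the list alone, with Gstm3 at -2.13 ± 0.24 (median -1.21; adjusted p = 0.162 with an estimated correlation). PPAR-alpha (median -0.58) and circadian genes (-0.51) shifted down with 2 members lower and 1 higher each, also over the list alone, among them Angptl4 (-2.70 ± 0.52), Acot1 (3.40 ± 0.26) and Npas2 (-2.14 ± 0.42). Their adjusted p was 0.365 with an estimated correlation, and both calls ended with quantile normalization (adjusted p = 0.0913 and 0.0753). Oxidative phosphorylation genes had a median of -0.17 with 0 of 22 called by limma, over all genes or the list alone (adjusted p = 0.640 with an estimated correlation). NF-kappaB targets and neutrophil markers were not called as lists (camera, adjusted p = 0.173 and 0.0688), although 11 and 5 members rose, such as Saa3 (5.10 ± 0.56), Lcn2 (5.44 ± 0.70) and S100a8 (at least 4.81 log2). Of the NF-kappaB targets 3 fell, Csf2 (adjusted p = 0.0354), Relb (-1.34 ± 0.31) and Tnfaip3 (-0.93 ± 0.27), named here after their values were seen. The count of 3777 genes was 2464 without the filter, 1945 and 2278 without the first and the second control non-tumour array, 2055 without the first control tumour array and 2058 without the second, which has the high Gapdh ratio. With a batch term 3299 were called. By fry 23 of the 40 lists were called. The circadian and PPAR-alpha calls ended without the second control non-tumour array (medians 0.15 and -0.56) and without the first control tumour array (-0.34 and -0.46), and so did that of oxidative phosphorylation (-0.08 and 0.03). The cholesterol synthesis call ended without the first control non-tumour array (0.87). The circadian and oxidative phosphorylation medians were -0.996 and -0.30 without that array and -0.29 and -0.34 without the second control tumour array.

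Tumour against non-tumour tissue in HAI-1 deficient mice gave 551 called genes, 321 higher and 230 lower. Serpina3n (at least 4.39 log2), Steap4 (at least 4.91-fold), Tff2 (5.29 ± 0.81 log2, SE, n = 2 per group, adjusted p = 0.0287), the matrix protein Mgp (at least 15.3-fold), Nptx2 (3.94 ± 0.31), and Alb (at least 6.89-fold) rose. So did the cartilage matrix genes Chad (at least 3.43-fold) and Col9a3 (at least 3.41 log2), though the mean of the Col9a3 probe sets was not called (2.27, adjusted p = 0.0834). Mast cell genes were among the largest rises, with the IgE receptor chain Fcer1a at least 9.45-fold and the protease Mcpt2 by 3.72 ± 0.71 log2. Without the first deficient tumour array Fcer1a was higher by at least 1.79 log2 and not called (adjusted p = 0.0563). Falls included Cyp2b10 (-3.57 ± 0.55), the vitamin C transporter Slc23a1 (-3.43 ± 0.58), Slc5a11 (-3.38 ± 0.65), Slc47a1 (-3.24 ± 0.59) and Rdh7 (-3.19 ± 0.37). Anpep (-3.14 ± 0.66), Cndp1 (at least 2.94 log2 lower), Acaa1b (-3.02 ± 0.50) and Hsd17b13 (-2.91 ± 0.57) fell as well, and Rdh16 was at least 6.58-fold lower. With the mean of probe sets the calls of Hsd17b13 (-2.22, adjusted p = 0.129), Anpep (0.0626), Slc5a11 (0.0527), Alb (0.0530), Fcer1a (0.0553) and Mcpt2 (0.0522) ended as well. Enterocyte genes fell in 9 of 26 (Slc15a1 -2.27 ± 0.30), or 16 over the list alone, and xenobiotic genes in 7 of 21 (Ces2a -2.46 ± 0.36), or 13 over the list alone. Their adjusted p with an estimated correlation was 0.142 and 0.0719. Over all genes 1 of 14 PPAR-alpha, 2 of 7 ileal, 1 of 19 enteroendocrine, 1 of 7 MHC class II and 1 of 16 T and natural killer genes fell, and 7, 5, 5, 4 and 6 did over the list alone. Their adjusted p with an estimated correlation was 0.142, 0.142, 0.302, 0.302 and 0.302, and it was 0.302 for circadian and 0.642 for oxidative phosphorylation genes, which shifted down with 0 called members. Rises were counted in 8 of 18 matrix, 6 of 16 fibroblast, 5 of 23 Wnt target, 4 of 8 mast cell, 3 of 29 cell cycle, 3 of 16 stem cell, 3 of 10 fetal-like and 2 of 12 smooth muscle genes. Over the list alone they were 15, 11, 17, 8, 19, 11, 4 and 8, with 1 stem cell gene lower, and the adjusted p with an estimated correlation was 0.264, 0.142, 0.302, 0.302, 0.425, 0.336, 0.302 and 0.304. Examples were Postn (at least 3.32 log2), Col1a2 (2.50 ± 0.25), Cd44 (1.75 ± 0.28) and Lgr5 (2.61 ± 0.48). With a batch term 406 genes were called. By fry 14 of the 40 lists were called. Of the called genes 321 were higher and 230 lower, against 199 and 217 with quantile normalization and 6 and 12 without the first deficient tumour array. Without that array the circadian call ended (median -0.16), and the T and natural killer and mast cell medians were -1.17 and 2.32, against -0.68 and 3.49 over all arrays. The circadian call also ended without the second deficient non-tumour array (-0.36), where the T and natural killer median was -1.18, and the oxidative phosphorylation call without the second deficient tumour array (-0.09). The count was 0 without the filter and in a fit to only the groups compared, 959 with the 60th percentile filter, 972 with a mean-variance trend, 205 with the mean of probe sets and 317 with array weights. It was 4 and 0 without the first and the second deficient non-tumour array, 18 and 73 without the first and the second deficient tumour array, 24 without either control non-tumour array and 346 without either control tumour array.

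Averaged over genotypes, 4697 genes differed between tumour and non-tumour tissue, 3366 higher and 1331 lower. Retnlb rose by 5.60 ± 1.13 log2 (SE, n = 4 arrays per tissue). Tff2, Nptx2, Tmem45a and Hp rose by at least 5.95, 4.80, 4.62 and 3.73 log2, and Serpina3n, Mgp, Alb, Pcolce2 and Steap4 at least 26.5-, 20.3-, 11.8-, 10.9- and 6.28-fold. Slc5a12 fell by at least 4.36 log2, or by 3.37 without the second control tumour array, Slc5a4b by at least 4.46, Slc23a1 by 3.82 ± 0.41, Slc5a11 by 3.75 ± 0.46 and Cubn by 3.70 ± 0.50. Slc5a4a fell by at least 3.66, Slc5a8 by at least 3.15 and the brush border peptidase gene Naaladl1 by 3.44 ± 0.70, while Slc34a2 was 13.1-fold and Rdh16 at least 6.20-fold lower. By camera 10 lists shifted up and 10 down, and 0 were called with an estimated correlation (smallest adjusted p = 0.114). By fry 25 of the 40 lists were called. Slc5a12 was not called without either control non-tumour or any 1 of the 4 deficient arrays (adjusted p = 0.0616 to 0.0934). Slc34a2 and Slc5a8 were not called without the first control non-tumour (0.0715 and 0.0663), the second deficient non-tumour (0.0703 and 0.0709) or the second deficient tumour array (0.0662 and 0.0652), nor Slc34a2 without the first deficient non-tumour array (0.0583). The circadian call ended without the second control non-tumour array (median 0.11). The interferon call ended without the first control tumour (-0.09), the first deficient non-tumour (0.03) or the second deficient tumour array (0.19).

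**Figure D4:**
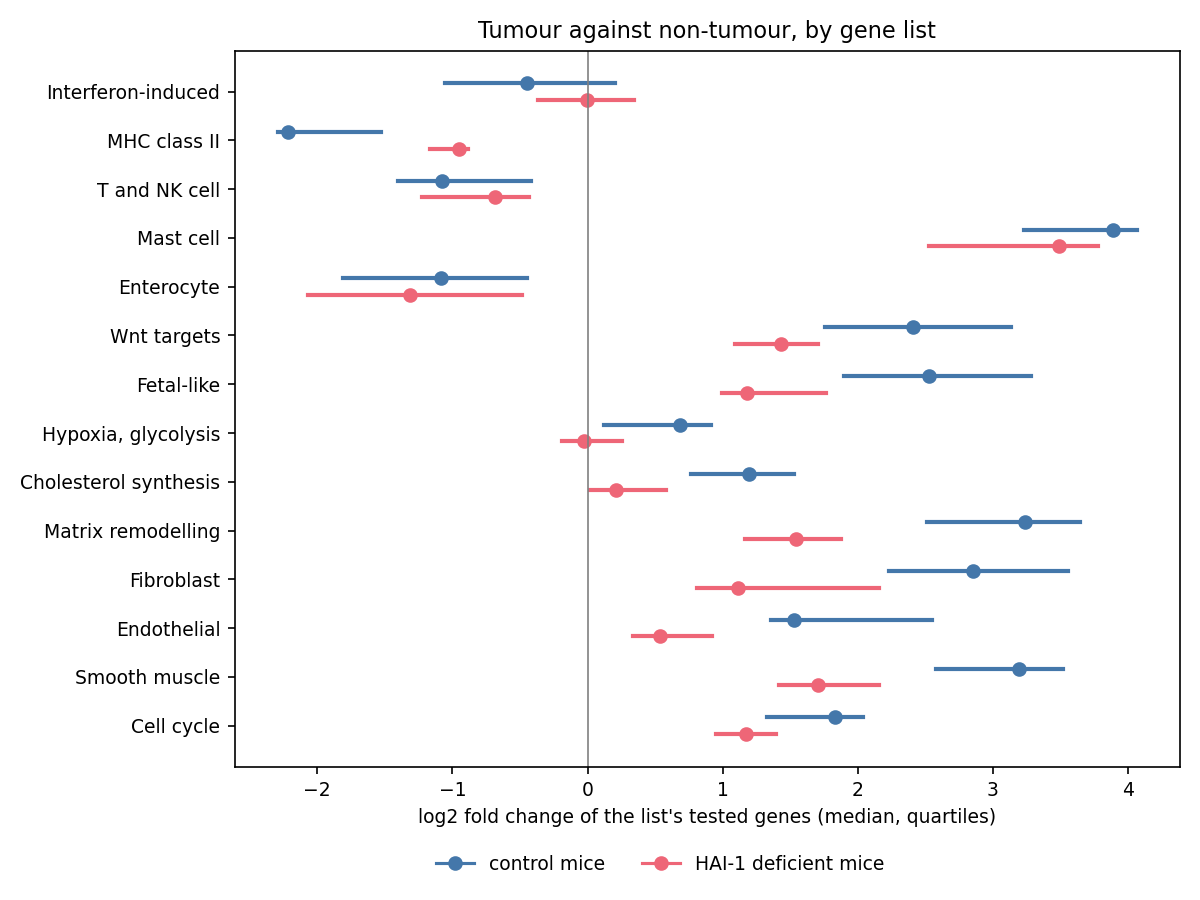
Median log2 difference of tumour against non-tumour tissue (horizontal axis) over the tested genes of 14 lists (vertical axis), in control and in HAI-1 deficient mice, with lines from the first to the third quartile of genes. Fibroblast genes had medians of 2.86 and 1.11, and Wnt targets of 2.41 and 1.44.

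The interaction tests whether HAI-1 loss had a different effect in tumours than in non-tumour mucosa. Limma called 0 genes (smallest adjusted p = 0.180), with 1211 at an unadjusted p under 0.05. Fry called 3 lists. Genes with the smallest p were Chil3 (-6.42 ± 0.68 log2), Acot1 (-3.18 ± 0.36), Tmem45a (-3.77 ± 0.51), Ncmap (-2.74 ± 0.34) and Fgfr1 (-2.55 ± 0.33) on the lower side, each with an adjusted p of 0.180 (SE, n = 2 per group). With the mean of probe sets Fgfr1 was at -1.20. On the higher side they were Ubd (3.72 ± 0.66), Tmem126b (3.06 ± 0.58), Cbx3 (2.36 ± 0.42), Mycbpap (2.23 ± 0.40) and Plaat3 (1.95 ± 0.35), each at 0.254. Chil3, Tmem45a and Ncmap had a mean under the filter value in control non-tumour mucosa and Tmem126b and Cbx3 in control tumours, so their sizes are not known. With each array under the filter value raised to it they were -1.92, -1.82, -2.12, 2.09 and 1.38, and Fgfr1 was at -2.54. Fibroblast genes had a median of -1.71 (camera, adjusted p = 3.28e-09; adjusted p = 0.119 with an estimated correlation), with 0 of 16 called over all genes and 10 adjusted over the list alone, such as Pdgfrb (-2.15 ± 0.39) and Col1a2 (-1.80 ± 0.36). Matrix genes had a median of -1.41 (6 of 18 over the list alone; adjusted p = 0.428 with an estimated correlation), with Mmp14 at -2.16 ± 0.39. MHC class II genes were at 0.96 (0 of 7; adjusted p = 0.513 with an estimated correlation) and interferon-induced genes at 0.47 (0 of 23; 0.613). The interferon call ended without the first deficient tumour array (median -0.06), and the median was 1.01 without the second, 0.88 and 0.19 without the first and the second deficient non-tumour array and 0.31 without the first control non-tumour array. In all, 3 lists shifted up and 10 down with the preset correlation and 0 with the estimated one.

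Genes called for HAI-1 loss in non-tumour mucosa overlapped those called in control tumours. Of the 118 that rose, 113 also rose in control tumours, among them Hp, Tmem45a and Notum, against 24.96 expected for independent lists. Of the 20 that fell, 13 fell in control tumours, among them Ubd, against 1.53 expected. Both comparisons use the same 2 control non-tumour arrays, so part of the excess may come from these shared controls. A split that gives each comparison 1 of these arrays was not run. Across genes, which are not independent replicates, the log2 differences had a Pearson's r of 0.67, a Spearman's rho of 0.66 and a covariance of 0.553. Simulated groups without change gave an r of 0.50 and a covariance of 0.101 from the shared arrays alone. Against HAI-1 loss in tumours, which shares no array, r was 0.29 and the covariance 0.109, and 77 of the 118 genes and all 20 had the same sign there. Between control and deficient mice, 309 of the 321 genes higher and 204 of the 230 lower in deficient tumours were also called in control tumours, against 67.9 and 17.6 expected. The group means compared here share no array, but every call uses the same spread per gene, fitted over the arrays of all groups. A gene with a small fitted spread is thus more readily called in both comparisons. This may add to the excess here and to that for HAI-1 loss in non-tumour mucosa. The counts expected for independent lists do not allow for it, so the size of either excess cannot be read from them.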

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

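Tests chosen only after the result was seen were both limits for the genes that fell, the comparison of interferon-induced with T and natural killer genes, the batch term for interferon-induced genes in tumours alone, and that of fibroblast with T and natural killer genes.

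For 13 gene lists, camera's test of the interaction called for a closer look at a difference between tissues in the effect of HAI-1 loss. The difference, in tumours minus non-tumour mucosa, had a median of -1.71 log2 for fibroblast (camera, adjusted p = 3.28e-09), -1.41 for matrix (9.36e-09), -1.44 for epithelial-mesenchymal transition (0.00446), -1.20 for endothelial (0.00172) and -0.93 for cholesterol synthesis genes (0.00172). It was -1.02 for Wnt targets (0.00024), -1.12 for fetal-like (0.00063), -0.68 for stem cell (0.0221), -0.62 for cell cycle (0.0221) and -0.65 for hypoxia genes (0.0348). On the other side were MHC class II genes (0.96, adjusted p = 0.00063), interferon-induced genes (0.47, 0.00063) and immediate early genes (0.27, 0.0308). With an estimated correlation 0 of the 13 passed, at an adjusted p of 0.119 for fibroblast genes, 0.428 for matrix and transition genes, 0.513 for fetal-like and MHC class II genes and 0.598 to 0.773 for the other 8. By fry the fibroblast and transition lists passed (adjusted p = 0.00809 each), the matrix list was at 0.0575, and the other 10 had an adjusted p of 0.139 to 0.649. With the mean of probe sets the transition, stem cell and immediate early calls ended, at medians of -0.55, -0.18 and 0.24 (camera, adjusted p = 0.0685 to 0.359). Single arrays ended calls: without the first deficient tumour array those of interferon-induced, stem cell, hypoxia and immediate early genes (medians -0.06, -0.81, -0.54 and 0.09), and without the second that of cell cycle genes (-0.40). Without the first control tumour array those of stem cell, cell cycle, immediate early and endothelial genes ended (-0.43, -0.41, -0.11 and -0.83). Without the first control non-tumour array those of stem cell, cell cycle, hypoxia and cholesterol synthesis genes ended (-0.50, -0.23, -0.45 and -0.73), and without the second that of immediate early genes (0.09). Without the first deficient non-tumour array that of hypoxia genes ended (-0.42), and without the second those of stem cell and cell cycle genes (-0.39 and -0.28). Among calls kept, the interferon median was 1.01 without the second deficient tumour array, 0.88 and 0.19 without the first and the second deficient non-tumour array and 0.31 without the first control non-tumour array. The Wnt median was -0.67 without the first deficient tumour array and the fetal-like median -0.63 without the first control tumour array. The endothelial median was -0.64 without the second control and -0.79 without the second deficient non-tumour array. The immediate early median was 0.71, 0.51 and 0.57 without the second control tumour, the first deficient non-tumour and the second deficient tumour array.

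Among 3949 probe sets with no listed gene or several, which the comparisons left out, 156 differed between tumour and non-tumour tissue of control mice, 105 higher and 51 lower, and averaged over genotypes 281 did, 166 higher and 115 lower. Limma called 0 of them for HAI-1 loss in either tissue, its average, the interaction, or tumour against non-tumour tissue in deficient mice. They show a signal outside the genes analysed, and no explanation was tested.

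The 118 genes that rose with HAI-1 loss in non-tumour mucosa included 113 that rose in control tumours, so tumour tissue in the non-tumour samples is a candidate explanation beside an effect of HAI-1 loss. For a mixture with deficient tumour as the cause of all these rises, each gene would imply about the same tumour share. The implied share (median 51.1%) had an SD on the log2 scale 3.34 times as large between genes as between the 2 arrays. Both arrays' shares use the same control and tumour means, so errors in these means widen only the spread between genes. Of the 118 genes, 7, among them Ddah1 and Cyp2d10, lay above both tumour groups by more than 2 standard errors. At least 1 in 20 had been set as the limit beforehand. The 118 were picked for their rise on these same deficient arrays, so neither result decides against the mixture. The 20 genes that fell had a median of -3.12, against -2.07 allowed by the 75th percentile of these shares (76.2%). This lies within the spread of the falls (interquartile range 1.27) and left the question open. Under a second limit, chosen after that outcome, the share came from 51 tumour marker genes (75th percentile 19.3%), which allows -0.31. The falls need a share of 88.5% at the median and 66.2% at the least, a level that 49 of the 51 markers stay under. However, the 20 genes were picked for their fall on these same deficient arrays, and only large falls are called with 2 arrays per group. The calling thus sets the least share in part, so the second limit cannot decide against tumour tissue as the cause of the falls. Quantile normalization left 93.6% of the median rise, and a batch term left 100%, which the design fixes, since either group has 1 array of each batch. An effect of HAI-1 loss stays a hypothesis. Tumour tissue as full or partial cause of the rises or the falls, microscopic tumours of another makeup, and differences in gut segment, litter or housing stay open.

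Interferon-induced genes had a median of -1.46 log2 with HAI-1 loss averaged over tissues and T and natural killer markers one of -1.09, so fewer of these cells is a candidate explanation beside an effect of HAI-1 loss. Averaged over tissues, the mean of the interferon list differed from that of the T and natural killer list by -0.57 (permutation over genes, p = 0.0328). The test treats genes as independent. In non-tumour mucosa the interferon median was lower than the T and natural killer median within the low spike-in batch (-1.57 against -1.11). The same held there within the high batch (-2.08 against -1.23). In tumours the order turned within the low batch, at -0.39 against -0.53. The difference thus argues against an equal loss of both with the cells in non-tumour mucosa at most, and leaves it open in tumours. Quantile normalization left 108% of the interferon median averaged over tissues, which argues against scaling as the cause. A batch term left 92.2%, which decides nothing, since the design fixes the non-tumour part of that average. In tumours alone a batch term left 74.8% and the low spike-in batch, which leaves out the second deficient tumour array, 35.4% (-0.39 against -1.11), so the batch or that array stays open as a cause of the fall there. A lower interferon signal from fewer T and natural killer cells, and differences in litter, housing or infection, were not tested, and an effect of HAI-1 loss stays a hypothesis.

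Fibroblast genes had a median of 1.16 log2 with HAI-1 loss in non-tumour mucosa and of -0.64 in tumours. The interaction's median kept 98.1% of its size without the control tumour array with the high Gapdh ratio and 91.4% with quantile normalization, which argues against RNA quality and scaling as the cause. The prediction for a lower epithelial share in deficient non-tumour mucosa was a like rise of fibroblast and T and natural killer markers. Their mean changes differed by 1.81 (permutation over genes treated as independent, p = 3e-05). Some T and natural killer cells lie within the epithelium and would be lost with it, so this difference cannot decide the question. A lower epithelial share and more stroma in the deficient mucosa stay open. So do tumour tissue in it and more of the gut wall in its samples (smooth muscle median 0.85). An effect of HAI-1 loss that differs between the tissues is a hypothesis, found and tested on the same data.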

How the results depend on the processing

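The spike-in batch term and the crossed replicate block were chosen after seeing the data. For HAI-1 loss in non-tumour mucosa the count of 138 genes was 46 with quantile normalization, 0 without the filter, 331 with the 60th percentile filter, 370 with a mean-variance trend, 24 with the mean of probe sets, 84 with the replicate block and 46 with only the groups compared. For its average over tissues, the count of 0 was 31 with the 60th percentile filter, 116 with the trend, 1 with the mean of probe sets, 19 with array weights and 1 with the replicate block. Spint1 passed there with the trend (-0.84, adjusted p = 0.0401, against 0.0686 to 0.302 under the other alternatives). For tumour against non-tumour tissue the count of 3777 in control mice was 2464 without the filter, and the count of 551 in deficient mice was 0 without the filter, 959 with the 60th percentile filter, 972 with the trend, 205 with the mean of probe sets, 317 with array weights, 341 with the replicate block and 0 with only the groups compared. Fits without the filter test more genes and fits to only the groups compared have fewer arrays; otherwise the cause was not tested. Counts for HAI-1 loss in tumours and the interaction were 0 by limma under every alternative run, with 334 to 1645 and 894 to 1382 genes at an unadjusted p under 0.05, and the average over genotypes stayed within 1.5 times of 4697. Leaving out each array in turn gave 0 to 171 genes for HAI-1 loss in non-tumour mucosa, 0 to 221 averaged over tissues, 1945 to 3767 for tumours in control mice, 0 to 346 in deficient mice and 3439 to 3996 averaged over genotypes; the arrays that move each count are named with it above. Spint1 ranged over the same fits from -0.69 to -0.48 in non-tumour mucosa, -1.25 to -0.95 in tumours and -0.92 to -0.77 averaged. In these fits the lone array of a group is assumed to vary like the other groups. No Spint1 value or named gene changed sign and no list's test turned, but the balance of called genes in deficient mice turned from 321 higher and 230 lower to 199 and 217 with quantile normalization and to 6 and 12 without the first deficient tumour array. Over the single genes named and their alternatives, 1462 of 1903 values kept direction and side of the threshold, 400 lost a call and 41 gained one. With quantile normalization Cbr3, Sgce, Tppp, Ido1, Afp, Usp18 and Ifit1 in deficient non-tumour mucosa (adjusted p = 0.0547 to 0.0801), Slc5a12 and Slc34a2 in control tumours and Fcer1a and Anpep in deficient tumours lost theirs. With the mean of probe sets 18 did: Cbr3, Eya2, Cldn18, Dio1, Tppp, Ido1, Kcnj13, Afp, Usp18 and Ifit1 in deficient non-tumour mucosa (0.0502 to 0.245), Slc34a2 in control tumours (0.0579) and Fcer1a, Alb, Col9a3, Mcpt2, Slc5a11, Anpep and Hsd17b13 in deficient tumours (0.0522 to 0.129). Of 1508 values for lists, 1236 kept their call and 272 lost it: 116 with an estimated correlation, 76 without single arrays, 59 by fry, 13 with the mean of probe sets and 8 with quantile normalization. The 13 were the tuft and stress lists in non-tumour mucosa, NF-kappaB and hypoxia in tumours, matrix averaged over tissues, circadian in all 3 tumour comparisons, PPAR-alpha in control mice, interferon averaged over genotypes, and stem cell, transition and immediate early genes in the interaction (adjusted p = 0.0588 to 0.359). Whether replicate numbers pair the samples is not known. The difference between the first and the second array correlated between groups at an r of -0.14 to 0.22, which cannot exclude pairing. The highest r was that of the 2 non-tumour groups, whose second arrays are both of the high spike-in batch. A log scale or pseudocount was not varied, since the table is already on the log2 scale. Without detection calls, the signal over background of dim genes is not known, which limits folds to lower bounds where a group lies under the filter value.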

Other observations

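The genes in this and the next paragraph were chosen from their lists after their values were seen. The goblet cell regulators Spdef (2.25 ± 0.25 log2, SE, n = 2 per group, adjusted p = 0.00183) and Creb3l4 (1.62 ± 0.38) rose in control tumours, as did Ern2, a stress sensor of mucus-producing cells (2.25 ± 0.30), and Reg4 (1.60 ± 0.36). The goblet list was not called (camera, adjusted p = 0.228; median 0.45, with 6 of 14 members higher). The hormone genes Sct (-2.11 ± 0.43, adjusted p = 0.0111) and Sst (-1.96 ± 0.43, adjusted p = 0.015) fell with the others named above. Of the tuft cell genes Avil (2.98 ± 0.34) and Alox5 (1.25 ± 0.39) rose and Ptpn6 (-1.29 ± 0.32) fell, and the tuft list was not called (camera, adjusted p = 0.446; median -0.08, with a mean or test of another sign). The antimicrobial lectin Reg3a fell by 4.08 ± 0.68 (adjusted p = 0.00575). The iron exporter Slc40a1 rose by 4.14 ± 0.92 (adjusted p = 0.0151).

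In the list of HAI-1, its target proteases and linked pathways, the plasminogen activator Plat (3.79 ± 0.42 log2, SE, n = 2 per group, adjusted p = 0.00178), Serpinb5 (2.34 ± 0.29), the HGF activator gene Hgfac (1.59 ± 0.34) and Prss8, which encodes the membrane protease prostasin (1.37 ± 0.27), rose in control tumours. The list was not called there (camera, adjusted p = 0.365; median 0.26), with 7 members higher, 1 lower, Mst1 (-0.96 ± 0.27), and 10 not called. In deficient tumours Serpinb5 rose by 1.69 ± 0.29 (adjusted p = 0.0309). The pore-forming claudin Cldn2 rose by 3.42 ± 0.28 and Cldn15 fell by 1.47 ± 0.39 in control tumours.

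The Y-linked genes Eif2s3y (10.14 to 11.37 log2), Kdm5d (8.53 to 9.40) and Uty (8.20 to 9.51) were above the filter value in all 8 arrays, and Xist was 6.32 at most, as in male mice. Pancreatic genes were not called as a list in any comparison, and 1 of 5, Cela1, rose in tumours of control (2.48 ± 0.35, adjusted p = 0.0036) and deficient mice (1.91 ± 0.35, adjusted p = 0.0367).

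Other splits of the 8 arrays into groups of 4 were fitted with the other factor kept in the fit; the split by that factor itself could not be fitted, which leaves 34 splits, the real one included. For HAI-1 loss averaged over tissues all 34 gave at least as many genes as the real 0 by limma, with 5 at most among the others. A real count of 0 fixes that outcome, so it decides nothing. At an unadjusted p under 0.05 the real split gave 2136 genes and the highest other 2073. For tumour against non-tumour tissue 1 of the 34, the real split, gave as many as 4697 genes and the highest other gave 0. That share is the smallest these splits can give, under 0.05, but in the other splits the difference between tissues adds to the residual spread, which lowers their counts.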
